A study of Mus musculus with 6 samples.

How the data were processed

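Gene expression was measured by RNA sequencing in 6 libraries of mouse leukemia cells, 3 from untreated mice and 3 from mice given doxycycline (dox) in their food for 3 days. Per the labels, the cells came from 1 leukemia, named A024, were sorted by flow cytometry from the marrow of Rag1 knockout animals, and gave RNA through a column kit. The series' design text counts a separate mouse for each library. The replicates are thus mice carrying the same leukemia, and p-values measure the spread between such mice, not between leukemias. Per the labels, the sort took GFP-high cells from untreated mice and GFP-mid cells from dox-treated mice, so gate and treatment changed together.

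The deposited values are whole-number counts of reads per gene, with an Entrez Gene identifier and a gene length for each row. Per the submitters' processing notes, CASAVA 1.8.2 and featureCounts were used and the genome build was mm9. The version of featureCounts, the aligner, the gene annotation and the strand setting are not given in the sources used here. Without a strand setting, reads of a gene and of a gene overlapping it on the other strand cannot be told apart, and counts of near-identical copies such as Serpina3f, Vpreb1, Ly6c2, Hspa1a, Hspa1b, Hba-a1 and Hbb-b1 are uncertain. The reference at hand was of another build, so it was used for gene names, transcript GC content and no coordinates. The table held 26286 genes, of which 24176 identifiers matched a current symbol and 2110 did not. The 6 per-sample files held counts identical to those of the series table, so exchanging one for the other gave no second result.

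Total counts per library ran from 14185203 to 15612435. Genes with too few counts were removed with filterByExpr at its default minimum count of 10, which left 12275 genes holding 99.93% of all counts. Counts were scaled by the trimmed mean of M values (TMM), with factors between 0.991 and 1.009, and levels are given as CPM on that scale. Groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with no covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Mean CPM values are given with the standard deviation (SD) over 3 libraries. Intervals of count ratios are exact binomial 95% intervals and cover counting error only.

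Before the data were examined, 31 gene lists were fixed from general knowledge, 21 on the biology of B cells, proliferation, metabolism and signalling, and 10 holding markers of other cell types or of cell handling. Of their 549 entries, 547 matched the table, 1 of them by an older symbol. Each list with at least 3 tested genes was compared with all other genes by camera of limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 29 lists. The same test was run with a correlation estimated from the data. The rotation test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, was run beside it. Members were also counted from the per-gene test, adjusted over all genes and again adjusted over the list alone.

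The genes named were set by a rule fixed at the same time. They are Pax5, and the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups. They further include the 4 members with the smallest p in the lists of Pax5-activated, Pax5-repressed, maturation and B cell receptor genes, the 3 members with the smallest p in every other biology list, and the 2 most abundant members of each marker list. Members behind a count of 5 or fewer are named as well. Some genes that the rule takes are not reported here. Other genes, including those named without values, the levels per library of Rag1 and H2-Ab1 and the lists on V(D)J recombination, lysosome, proteasome, cohesin and ATF4 targets, were chosen after their values had been seen.

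The alternatives planned beforehand were DESeq2 size factors, upper-quartile scaling, total counts alone, no low-count filter, a minimum of 1 CPM in 3 libraries, the DESeq2 1.42.0 test, limma voom, the replicate number as a block, leaving out each library in turn, a minimum fold change of 1.5, and other set tests. An offset for gene length and GC content was added after the data had been seen. The scripts were tested on simulated counts made from these libraries, with 200 of the genes changed. Of 12168 genes tested there, 67.2% of those changed 1.5-fold, 86.4% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 13 of 181 calls (7.18%) were false. Shares of recovered genes and of false calls depend on how many genes change. In the real comparison 53.6% of the genes tested were called, far more than were changed here, so these shares need not hold for it. With no gene changed, edgeR called 0 of 12275 genes. In simulated lists, camera with the preset correlation called 10 of 10 lists changed 1.3-fold and 1 of 100 unchanged lists. The simulated genes varied independently and the lists were filled at random. These shares therefore do not measure the errors of camera for real lists, whose members can vary together. Figures were drawn with matplotlib 3.10.9.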

Results

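Cells of an acute lymphoblastic leukemia of B cell progenitors were profiled in mice in which Pax5, the transcription factor that commits lymphoid progenitors to the B lineage, can be switched back on. The labels used here name tri-transgenic mice, doxycycline (dox) and Pax5 restoration but do not describe the construct. As background from general knowledge of the published model, a tetracycline-regulated short hairpin RNA against Pax5 is transcribed together with GFP and is shut off by dox, an antibiotic given in the food. The comparison addressed how gene expression in established leukemia changes when Pax5 returns. It set 3 libraries from untreated mice (0 days of dox, GFP-high cells) against 3 libraries from mice given dox for 3 days (GFP-mid cells). Total counts were 14185203, 15053258 and 14630420 in untreated replicates 1, 2 and 3, and 15259422, 14432213 and 15612435 in dox replicates 1, 2 and 3. The first principal component held 76% of the variance and separated the groups. Correlations of log2 CPM across genes lay between 0.985 and 0.993 for the 6 pairs of libraries within a group, and between 0.939 and 0.959 for the 9 pairs across groups. Genes are not independent replicates, so these correlations describe the libraries only.

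Pax5 (Entrez Gene 18507) rose about 2.1-fold after dox. Its level was 117.5 ± 32 CPM in untreated mice and 246.3 ± 30.2 CPM after 3 days (SD, n = 3 each). Counts were 2200, 1393 and 1547 in the untreated libraries and 3452, 4039 and 3601 in the dox libraries, so that every dox library lay above every untreated one. The log2 fold change was 1.07 (SE 0.17, adjusted p = 0.000695, edgeR quasi-likelihood test). An exact two-sided permutation test of the CPM values gave p = 0.1, the smallest value that 3 libraries against 3 allow. Pax5 was thus measured at 93.5 CPM or more before dox as well. No dox-treated control without the hairpin was analysed here, so effects of the drug and of the sort gate are part of each difference below.

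**Figure D1:**
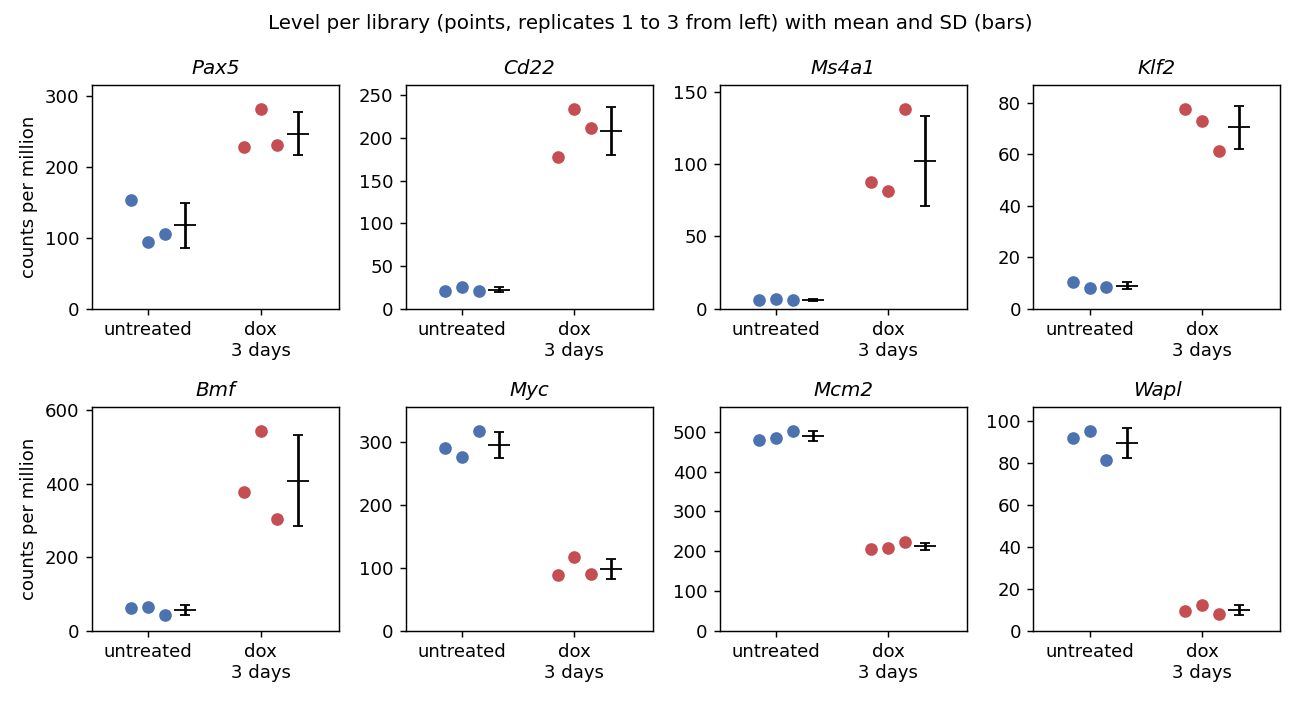
Level in CPM (y axis, linear, from 0) of 8 genes in the 3 untreated (blue) and 3 dox (red) libraries, with the group mean and SD as black bars. Pax5 lies between 93.5 and 153.8 CPM in untreated and between 227.2 and 281.2 CPM in dox libraries, and the groups of all 8 genes are separate.

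After dox, 3316 genes were higher and 3266 were lower among 12275 tested, together 53.6% of them. The change reached 2-fold for 966 of the higher and 474 of the lower genes. Groups did not overlap for 7640 genes (62.2%), against 10% by chance for 3 libraries against 3. The largest rise that the rule picked was that of Col5a3 (Entrez Gene 53867), a fibrillar collagen chain, from 4 counts in all untreated libraries to 1395 in all dox libraries, a ratio of 339 (95% interval 132 to 1250). Tmc5 (74424), a transmembrane channel-like gene, went from 3 to 495 counts, a ratio of 160 (54.6 to 781). All untreated counts of Tmc5 came from replicate 1, with 0.21, 0 and 0 CPM in untreated replicates 1, 2 and 3. Serpina3f (238393), a serine protease inhibitor gene with close paralogs, went from 10 to 623 counts, and Plb1 (665270), a phospholipase gene, from 8 to 351. Cdhr2 (268663), a cadherin family gene, rose from 0.526 ± 0.376 to 29.2 ± 12.1 CPM and Ltbp2 (16997), an extracellular matrix gene, from 0.931 ± 0.399 to 35.4 ± 13.4 CPM (SD, n = 3).

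The deepest fall by the same rule was that of Ccl9 (20308), a chemokine gene, from 14.3 ± 3.09 to 0.702 ± 0.246 CPM (log2 fold change −4.32, SE 0.28). Wapl (218914), which releases cohesin from chromatin, fell from 89.7 ± 7.24 to 9.94 ± 2.24 CPM (−3.18, SE 0.14). St6galnac2 (20446), a sialyltransferase gene, changed by −2.63 (SE 0.28), Adamts17 (233332), a metalloprotease gene, by −2.58 (SE 0.34), and Ramp1 (51801), part of a neuropeptide receptor, by −2.50 (SE 0.35). Gm19639 (100503332), a predicted gene, changed by −2.35 (SE 0.37). All 12 genes had adjusted p of 0.000694 or less (edgeR).

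**Figure D2:**
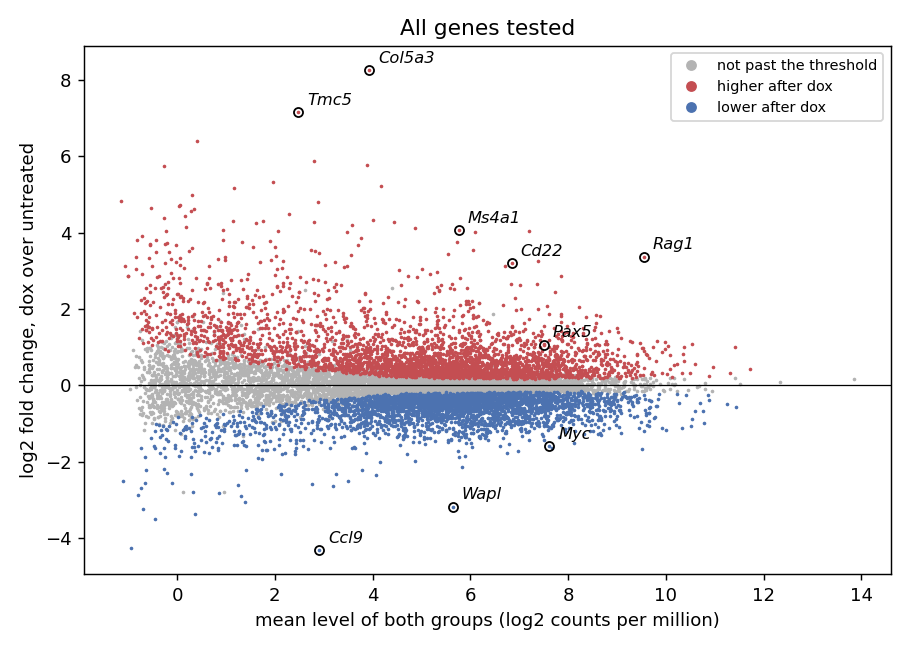
Log2 fold change of dox over untreated (y axis) against the mean level of both groups in log2 CPM (x axis), 1 point per gene, for 12275 genes. Red points are the 3316 genes higher and blue points the 3266 genes lower after dox, and circles mark 9 genes that the text names.

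Genes known to be activated by Pax5 rose together. Of 24 measured, 22 rose and 2, Cplx2 (log2 fold change −0.01) and Id3 (−0.18), did not pass the test, and the count adjusted over the list alone was also 22. Cd22, an inhibitory co-receptor of the B cell receptor, rose 9.18-fold (log2 fold change 3.20, SE 0.13), Siglecg, a related lectin, by 2.43 (SE 0.17), Bst1, a surface enzyme of early B cells, by 1.54 (SE 0.10), and Nedd9, an adhesion adaptor, by 0.90 (SE 0.07). The median was 0.89 (limma camera adjusted p = 6e-09, and adjusted p = 0.206 with an estimated correlation).

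Genes known to be repressed by Pax5 did not move as a group. Of 16 measured, 5 rose (Csf1r, Lmo2, Prdm1, Notch1 and Xbp1), 4 fell (Ccl9, Ramp1, Jchain and Grap2) and 7 did not pass, with the same counts adjusted over the list alone. Prdm1, a regulator of plasma cell fate, rose by 0.87 (SE 0.12) and Lmo2, a progenitor transcription cofactor, by 1.77 (SE 0.29), while Ccl9 and Ramp1 were among the deepest falls. The median was 0.21 and the mean −0.08, of opposite sign, and camera gave adjusted p = 0.739. The median was 0.32 without untreated replicate 1 and 0.08, 0.04 and 0.34 without dox replicates 1, 2 and 3. Csf1r, the receptor of macrophage growth factor, is also a member of the macrophage list described further on, which was higher after dox.

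Genes of B cell maturation were higher after dox. Of 24 measured, 20 rose and 4 did not pass, among them Ccr7, Il2ra and Ly6d, with 20 also adjusted over the list alone. Ms4a1, which encodes CD20, rose from 6.12 ± 0.394 to 102.3 ± 31.1 CPM (SD, n = 3). Klf2, a factor of resting lymphocytes, rose by 2.97 (SE 0.13) on the log2 scale, and Tnfrsf13c, the receptor of the survival factor BAFF, by 2.22 (SE 0.12). Cd22 counts in this list as well. The median was 1.24 (camera adjusted p = 1.13e-08, and adjusted p = 0.206 with an estimated correlation).

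Genes of B cell receptor signalling were higher too, 20 of 27 measured, while 1, Plcg2 (−0.25), fell. Adjusted over the list alone, 22 rose and 1 fell. The kinase gene Lyn rose by 1.66 (SE 0.07), the adaptor gene Pik3ap1 by 2.07 (SE 0.14) and Cd79b, a signalling chain of the receptor, by 1.15 (SE 0.08), beside Cd22. The median was 0.60 (camera adjusted p = 1.36e-07, and adjusted p = 0.206 with an estimated correlation). The fall of Plcg2 was not called without untreated replicate 2, without untreated replicate 3 or without dox replicate 1, each of which left 0 members lower.

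Among 17 genes of pro-B cells and progenitors, 7 rose, 1 (Runx1, −0.77) fell and 9 did not pass, with the same counts adjusted over the list alone. Rag2, a subunit of the V(D)J recombinase, rose from 1.52 ± 1.5 to 30.7 ± 3.92 CPM, Erg, an ETS factor, by 1.22 (SE 0.06) and Vpreb1, a surrogate light chain, by 0.81 (SE 0.07). Untreated replicates 1, 2 and 3 held 3.22, 0.34 and 1.02 CPM of Rag2, so its untreated mean rests largely on replicate 1. The median was 0.24 (camera adjusted p = 0.0419, and adjusted p = 0.347 with an estimated correlation). Without untreated replicate 2 or dox replicate 2 the list's adjusted p was 0.0673 or 0.0714, past the threshold in neither case, nor at 0.0541 with the length and GC offset, and without dox replicate 2 the members lower were 3 (Runx1, Cd93 and Il7r).

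Of 28 transcription factors of lymphoid cells, 19 rose, 2 (Gfi1b and Runx1) fell and 7 did not pass, alike when adjusted over the list alone. Klf2 and Erg had the smallest p values, followed by Tcf4, an E protein, which rose by 0.56 (SE 0.06). Pax5 is itself a member. The median was 0.47 (camera adjusted p = 7.99e-05, and adjusted p = 0.206 with an estimated correlation).

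In the MHC class II pathway, which presents antigen to T cells, 4 of 10 genes rose (H2-Oa, Cd74, H2-Ob and H2-Aa), or 3 adjusted over the list alone. H2-Ob rose by 1.54 (SE 0.14), H2-Oa by 2.01 (SE 0.24) and Cd74, the invariant chain, by 1.84 (SE 0.25). The classical gene H2-Ab1 measured 178.5, 136.9 and 134.6 CPM in untreated and 227.1, 137.6 and 184.4 CPM in dox replicates 1, 2 and 3. The median was 0.43 (camera adjusted p = 0.0309, and adjusted p = 0.599 with an estimated correlation). Cd74 measured 866.8, 411.7 and 515.7 CPM in dox replicates 1, 2 and 3, the order that neutrophil markers also followed there. The list's adjusted p was 0.0799 without dox replicate 1, with a median of 0.20, and 0.056 without untreated replicate 3.

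Genes of DNA replication and mitosis fell without exception in the lists tested. All 29 genes of S phase and all 24 genes of G2 and M phase were lower after dox, also when adjusted over the list alone. Mcm2, a subunit of the replicative helicase, fell from 488.8 ± 12.2 to 211.7 ± 9.38 CPM (SD, n = 3), E2f1, a driver of S phase, changed by −1.41 (SE 0.08) and Cdc6, a replication licensing factor, by −1.40 (SE 0.08). In G2 and M phase, Mki67, which encodes the Ki-67 antigen, fell from 2338 ± 255 to 1182 ± 125 CPM, Aurkb, a mitotic kinase, changed by −1.03 (SE 0.10) and Kif11, a spindle motor, by −1.12 (SE 0.13). The medians were −1.25 for S phase (camera adjusted p = 5.11e-18, and adjusted p = 0.206 with an estimated correlation) and −0.91 for G2 and M phase (camera adjusted p = 1.42e-09, and adjusted p = 0.396 with an estimated correlation).

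Of 16 genes that restrain the cell cycle, 9 rose, 3 (Rbl1, Cdkn1a and Cdkn2c) fell and 4 did not pass, alike when adjusted over the list alone. Btg1, an antiproliferative gene, rose by 1.81 (SE 0.15) beside Klf2, whereas Rbl1, which encodes the p107 pocket protein and is itself a target of E2F factors, changed by −0.96 (SE 0.07). As a group the list did not pass the test (median 0.32, camera adjusted p = 0.104), and its adjusted p was 0.0224 when ranked by the DESeq2 test and adjusted p = 0.344 with an estimated correlation.

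All 24 genes of the list of Myc and ribosome biogenesis fell, with the same count adjusted over the list alone. Myc, the oncogenic transcription factor, fell from 294.3 ± 20.9 to 98.1 ± 15.9 CPM (SD, n = 3). Srm, a polyamine synthesis enzyme, changed by −1.22 (SE 0.08), Polr1b, a subunit of RNA polymerase I, by −1.05 (SE 0.07) and Gnl3, a nucleolar GTPase, by −1.22 (SE 0.08). The median was −0.76 (camera adjusted p = 8.36e-12, and adjusted p = 0.206 with an estimated correlation).

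**Figure D3:**
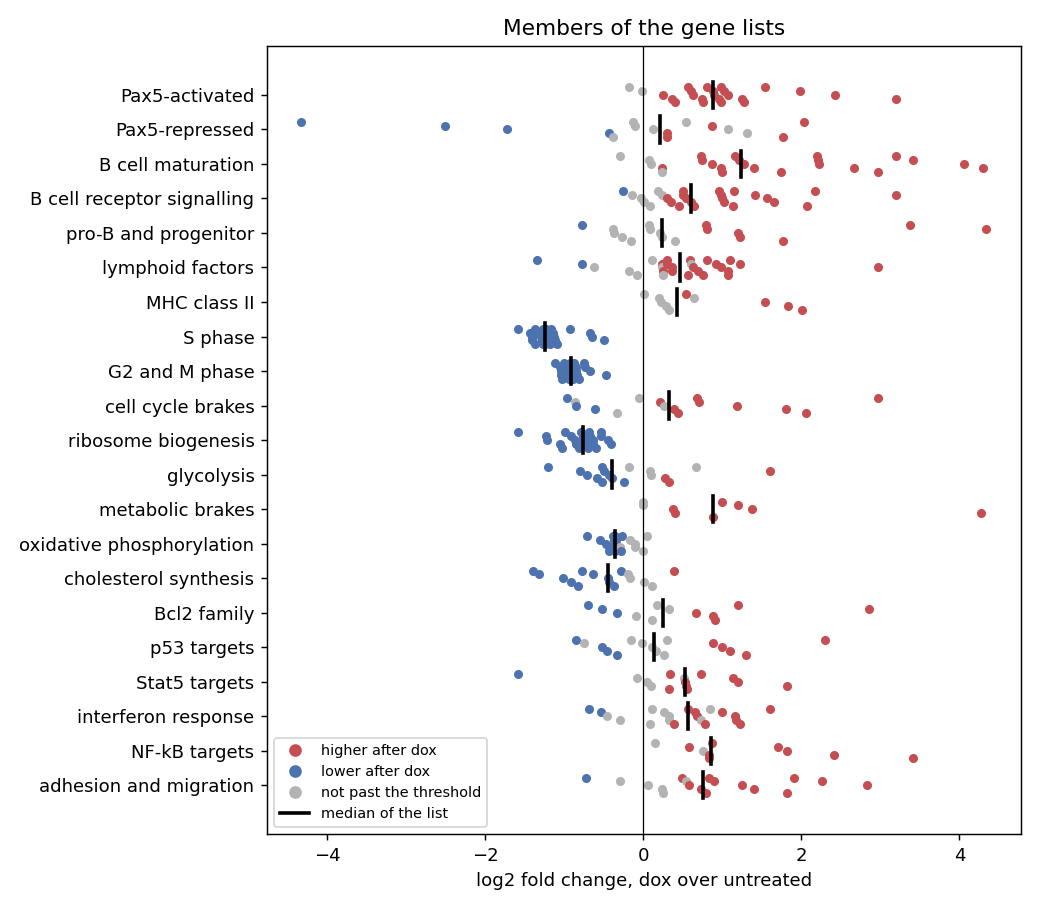
Log2 fold change of dox over untreated (x axis) of each tested member of the 21 biology lists (rows), in red where higher, blue where lower and grey where not past the threshold, with the list median as a black line. All 29 S phase, 24 G2 and M phase and 24 ribosome biogenesis genes lie below 0, and 22 of 24 Pax5-activated genes are higher.

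Metabolic genes changed in both directions. Of 17 glycolysis genes, 10 fell and 3 (Slc2a6, Hk1 and Aldoa) rose, also adjusted over the list alone. Hk2, a hexokinase, changed by −1.20 (SE 0.09), Tpi1 by −0.80 (SE 0.10) and Pgam1 by −0.59 (SE 0.08). The glycolysis list had a median of −0.40 and missed the threshold (camera adjusted p = 0.0656). It passed at 0.0437 without untreated replicate 1, 0.0359 without dox replicate 3, 0.0222 with no low-count filter, 0.049 at 1 CPM in 3 libraries, 0.0379 with the DESeq2 test and 0.0468 with the replicate block, but not without any of the other libraries (0.0714 to 0.0858), and had adjusted p = 0.428 with an estimated correlation. Of 9 genes described as metabolic brakes under Pax5, 7 rose and 2 did not pass (Stk11 and Nr3c1), also adjusted over the list alone. Cnr2, a cannabinoid receptor, rose by 4.28 (SE 0.46), Txnip, an inhibitor of glucose uptake, by 1.20 (SE 0.11) and Sesn1, a restraint on mTORC1, by 1.00 (SE 0.08). Their median was 0.88 (camera adjusted p = 0.00314, and adjusted p = 0.206 with an estimated correlation).

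Of 21 genes of oxidative phosphorylation, 15 fell and 6 did not pass, also adjusted over the list alone. Sdhc, in complex II, changed by −0.55 (SE 0.07), Cox5a, in complex IV, by −0.43 (SE 0.07) and Ndufa5, in complex I, by −0.70 (SE 0.11). The median was −0.35 (camera adjusted p = 0.00024, and adjusted p = 0.428 with an estimated correlation). Of 16 genes of cholesterol synthesis and uptake, 11 fell and 1, Mvd, rose, also adjusted over the list alone. Idi1, an isomerase of the mevalonate pathway, changed by −1.32 (SE 0.11) and Sqle by −1.02 (SE 0.12). The median was −0.44 (camera adjusted p = 0.0019, and adjusted p = 0.421 with an estimated correlation). The rise of Mvd was not called without untreated replicate 1, without untreated replicate 2 or without dox replicate 1, each of which left 0 members higher.

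In the Bcl2 family, which governs apoptosis, genes known to promote and genes known to prevent cell death rose. Of 12 genes measured, 5 rose (Bmf, Bcl2l1, Bcl2l11, Bcl2l2 and Mcl1), 3 fell (Bid, Pmaip1 and Bax) and 4 did not pass, also adjusted over the list alone. Bmf, a pro-apoptotic BH3-only gene, rose from 56.1 ± 12.5 to 407.8 ± 124 CPM (SD, n = 3), Bcl2l11, which encodes the pro-apoptotic Bim, by 0.91 (SE 0.08) and Bcl2l1, which encodes the protective Bcl-xL, by 1.20 (SE 0.10). The family did not pass as a group (median 0.25, camera adjusted p = 0.166), and its median was 0.03 without untreated replicate 2, 0.40 without dox replicate 2 and 0.48 without untreated replicate 1. Of 16 p53 targets, 5 rose (Plk2, Gadd45a, Trp53inp1, Sesn1 and Sesn2), 4 fell (Cdkn1a, Pmaip1, Aen and Bax) and 7 did not pass, also adjusted over the list alone. Trp53inp1 rose by 1.10 (SE 0.10) and Gadd45a by 1.31 (SE 0.14), and the list did not pass (median 0.14, camera adjusted p = 0.497). Its median was 0.06 without untreated replicate 2 and 0.01, 0.28 and 0.05 without dox replicates 1, 2 and 3.

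Among 14 targets of Stat5, a cytokine signal transducer, 9 rose and 1, Myc, fell, or 10 and 1 adjusted over the list alone. Cd69, a lymphocyte activation marker, rose by 1.82 (SE 0.10), beside Bcl2l1. The median was 0.52 (camera adjusted p = 0.0318, and adjusted p = 0.428 with an estimated correlation). The number higher was 4 without untreated replicate 3 (Cd69, Bcl2l1, Osm and Pim1) and 5 without untreated replicate 2 (the same and Ccnd2), and without dox replicate 2 the adjusted p was 0.0668 and the median 0.34.

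Of 10 targets of NF-kB, 8 rose and 2 did not pass (Tnf and Nfkb1), or 9 rose adjusted over the list alone. Relb, a subunit of NF-kB, rose by 2.41 (SE 0.20), Birc3, an inhibitor of apoptosis, by 1.71 (SE 0.12) and Icam1, an adhesion molecule, by 0.83 (SE 0.08). The median was 0.85 (camera adjusted p = 0.00014, and adjusted p = 0.206 with an estimated correlation). Of 18 adhesion and migration genes, 12 rose and 1, Itga6, fell, also adjusted over the list alone. Sdc4, a heparan sulfate proteoglycan, rose by 1.25 (SE 0.10), beside Cd69 and Nedd9. The median was 0.76 (camera adjusted p = 0.000134, and adjusted p = 0.206 with an estimated correlation). Vcam1, another riser of this list, is also a macrophage marker.

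Of 21 interferon-response genes, 10 rose and 2 (Ifit2 and Ifih1) fell, or 11 and 2 adjusted over the list alone. Mx2 rose by 1.18 (SE 0.16), and Ifit2 changed by −0.69 (SE 0.09). The list missed the threshold (median 0.57, camera adjusted p = 0.0656). Without dox replicate 1, 7 rose and 4 fell (Ifit2, Ifih1, Irf7 and Isg15), and without dox replicate 2, 16 rose and the adjusted p was 0.00174. The median was 0.24 without dox replicate 1. The list also passed with the replicate block (0.0189), no low-count filter (0.041) and the DESeq2 test (0.044), but had adjusted p = 0.717 with an estimated correlation.

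Markers of myeloid cells were higher after dox. Of 11 neutrophil genes, 10 rose (median 1.51, camera adjusted p = 0.0309, and adjusted p = 0.6 with an estimated correlation), with the same count adjusted over the list alone. The summed level of the list was 138, 108 and 131 CPM in untreated and 642, 144 and 305 CPM in dox replicates 1, 2 and 3. S100a9 measured 39.1, 29.9 and 29.3 CPM in untreated and 169.9, 31.2 and 78.2 CPM in dox replicates, and S100a8 rose from 19.1 ± 4.09 to 62.1 ± 41.9 CPM (SD, n = 3). The number higher was 5 without dox replicate 1 (Itgam, Lcn2, Ltf, Ngp and S100a8, with a list median of 0.80) and 4 without untreated replicate 2 (the same without Ngp). The rise of S100a9 was not past the threshold without untreated replicate 2 (adjusted p = 0.074), untreated replicate 3 (0.0775) or dox replicate 1 (0.0793). Of 12 macrophage and monocyte genes, 9 rose, or 10 adjusted over the list alone (median 2.18, camera adjusted p = 0.00144, and adjusted p = 0.396 with an estimated correlation). Their sum was 18.2, 10.4 and 11.4 CPM in untreated and 58.7, 41.2 and 37.7 CPM in dox libraries. Vcam1 rose from 1.40 ± 1.06 to 9.97 ± 1 CPM, and Cd68 measured 3.62 ± 0.427 and 4.30 ± 0.148 CPM (adjusted p = 0.286).

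**Figure D4:**
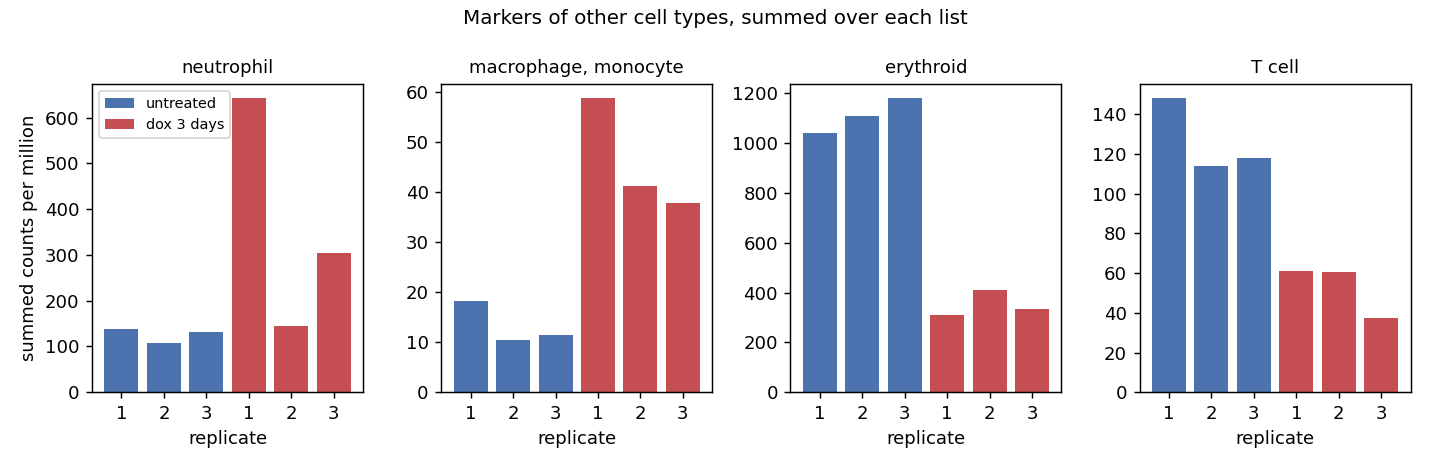
CPM summed over the genes of 4 marker lists (y axes, linear, from 0, each with its own scale) in the 3 untreated (blue) and 3 dox (red) libraries. Neutrophil markers reach 642 CPM in dox replicate 1 and 144 CPM in dox replicate 2, macrophage and monocyte markers lie between 37.7 and 58.7 CPM in all dox libraries, and the erythroid sum consists mostly of Car2.

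Other marker lists did not pass as groups. Of 4 erythroid genes, 1 fell, Car2, a carbonic anhydrase gene, from 1106 ± 69.1 to 346.6 ± 55.5 CPM, while Hbb-b1 measured 1.71 ± 0.437 and 1.62 ± 1.25 CPM (list adjusted p = 0.144). Without dox replicate 1, 2 of them (Car2 and Hba-a1) were lower. Of 4 T cell genes, 1 fell, Lat, an adaptor of antigen receptors, from 99.1 ± 7.2 to 32.1 ± 14.1 CPM, and Bcl11b measured 17.5 ± 20.1 and 8.58 ± 8.01 CPM (list adjusted p = 0.687). Of 6 plasma cell genes, 3 rose (Prdm1, Xbp1 and Mzb1) and 2 fell (Sdc1 and Jchain), with a median of −0.03 (0.07 without untreated replicate 3 and 0.13 without dox replicate 3), a camera direction upward and adjusted p = 0.987. Mzb1 rose by 0.35 (SE 0.10) and Xbp1 by 0.30 (SE 0.08). Without untreated replicate 2, 1 plasma cell gene, Prdm1, was higher, and neither Mzb1 (adjusted p = 0.0579) nor Xbp1 (0.0536) passed. Xbp1 stood at 0.0506 without untreated replicate 3.

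Of 4 plasmacytoid dendritic cell genes, 2 rose (Itgax and Ly6c2, the latter by 1.67, SE 0.55), Bst2 measured 21.5 ± 2.43 and 23.3 ± 8.72 CPM, and the list had adjusted p = 0.379. Of 3 genes of stroma and endothelium, 2 rose, Pecam1 by 0.58 (SE 0.09) and Col1a1 by 1.13 (SE 0.42), and the list had adjusted p = 0.133. Of 2 natural killer genes, too few for the list test, Prf1 rose by 1.52 (SE 0.56) and Klrb1c measured 3.66 ± 0.916 and 4.53 ± 4.04 CPM. Each of the rises of Ly6c2, Col1a1 and Prf1 lost its call in several fits with a library left out. Ly6c2 was not called without dox replicate 1 (adjusted p = 0.0976) or any untreated replicate (0.0765, 0.0597 and 0.0881). Col1a1 was not called without untreated replicate 2 (0.15) or 3 (0.132) or dox replicate 1 (0.0526) or 2 (0.163). Prf1 was not called without untreated replicate 1 (0.13) or 2 (0.141) or dox replicate 1 (0.101) or 3 (0.128). None of the 9 megakaryocyte genes had enough counts to be tested.

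Of 12 genes of the immediate early and stress response, a sign of cell handling, 7 rose and 2 (Dusp1 and Ier2) fell, also adjusted over the list alone, while without untreated replicate 2 only 1, Ier2, was lower. Btg2 rose from 116.3 ± 34.2 to 485.6 ± 52.4 CPM (SD, n = 3) and Zfp36 by 0.35 (SE 0.13), the latter at adjusted p between 0.103 and 0.146 in 4 of the 6 fits that leave out a library. The list did not pass (median 0.73, camera adjusted p = 0.0635), and did at 0.0437 without untreated replicate 1, 0.0359 without dox replicate 3, 0.0345 with no low-count filter and 0.0357 with the replicate block, but had adjusted p = 0.344 with an estimated correlation. The median was 0.31 without untreated replicate 3. The sums were 414, 314 and 326 CPM in untreated and 956, 856 and 753 CPM in dox replicates 1, 2 and 3.

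In all, 17 of 29 lists passed camera with the preset correlation, 12 higher and 5 lower. None of these calls held with an estimated correlation, where 0 lists passed after adjustment and 6 had an unadjusted p under 0.05, while fry, which does not compare with other genes, called 21. Against camera, fry lacked MHC class II (0.0772) and the neutrophil markers (0.172) and added cell cycle brakes (0.000588), glycolysis (0.00844), the Bcl2 family (0.0173), immediate early genes (0.00523), erythroid (0.0055) and stroma and endothelium genes (0.0185).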

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

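The offset for gene length and GC content was chosen after the data had been seen, and the other alternatives before. The fits without dox replicate 1 were among the latter, and its choice as a library in doubt came after. Pax5 rose under every setting, with log2 fold changes from 0.92 without untreated replicate 2 to 1.31 without untreated replicate 1. The genes higher and lower were 3272 and 3287 with DESeq2 size factors, 3534 and 3073 with upper-quartile scaling, 3257 and 3291 with total counts alone, 3174 and 3441 without a low-count filter, 3274 and 3204 at 1 CPM in 3 libraries, 3000 and 3126 with the DESeq2 test, 3269 and 3262 with limma voom, and 3128 and 3098 with the length and GC offset, which has a value for 88.3% of the genes. Leaving out a library gave 2693 to 3168 higher and 2791 to 3193 lower. Of the 6582 calls, 81.8% to 99.3% were shared in the same direction under these settings and 0 were reversed. The median log2 fold change of all genes stayed between −0.02 and 0.04. Every scaling used makes levels relative to the other genes of a library, so a median near 0 is largely built in. Rises and falls are thus relative, and a change in total RNA per cell cannot be seen. A minimum fold change of 1.5 left 928 higher and 670 lower, since it asks for a larger effect. Of 29 lists, 0 passed camera with an estimated correlation, against 17 with the preset one, and the cause was not tested. Lists that share the value 0.206 do so through the Benjamini-Hochberg adjustment, so it does not rank them. How often this variant finds a list that has changed was not simulated.

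The replicate numbers do not pair the mice by the labels, and same-numbered libraries deviated from their group means with correlations of 0.31, 0.29 and −0.04. A fit with the replicate number as a block gave 3434 genes higher and 3356 lower, 20 lists (the 17, glycolysis, interferon response and immediate early genes) and a Pax5 log2 fold change of 1.09. As a hint from the data and not from the design, 4 of 6 libraries correlated best with the library of their own number. The second principal component, with 10.3% of the variance, also ranked the replicates alike in both groups. Replicates 1, 2 and 3 stood at 17.8, −12.5 and −0.8 in untreated and at 15.4, −23.3 and 3.3 in dox libraries.

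The plasma cell list, never past the threshold, turned downward with upper-quartile scaling (adjusted p = 0.963), the DESeq2 test (0.781) and fry (0.361), and without untreated replicate 1 (0.941) or 2 (0.911) or dox replicate 1 (0.853) or 2 (0.883), and stayed upward without untreated replicate 3 (0.98) or dox replicate 3 (0.726). Genes not called in the main fit also changed sign. Klrb1c stood at −0.048 with limma voom and between −0.73 and 0.65 on leaving out a library, Hbb-b1 between −0.83 and 0.35, Bcl11b between −2.11 and 0.47, and Bst2 between −0.14 and 0.38. Of these, Bcl11b was called with the replicate block (adjusted p = 0.0263) and Bst2 without dox replicate 2 (0.0281). The cause was not tested. Besides the fits without a library, calls were lost for Zfp36 (total counts alone, 0.0508, limma voom, 0.0561), S100a9 (DESeq2, 0.0577, voom, 0.0764), Prf1 (no low-count filter, 0.0533, DESeq2, 0.0984), Ly6c2 (voom, 0.0757) and Col1a1 (no low-count filter, 0.0511, DESeq2, 0.0841, voom, 0.0508, the offset, 0.0789). Of 1287 comparisons of a setting with the 86 genes besides Pax5 that the rule takes, 1244 kept direction and side of the threshold, 33 lost and 2 gained a call, and 8 changed sign. For the lists under settings other than the set test these were 377 of 404, 6, 15 and 6. Planned exchange of the deposited tables gave no value, since they were identical, and limma voom is part of camera and adds none for the lists. At this depth the ratios of rare genes stay imprecise, as for Col5a3 and Tmc5 with 4 and 3 untreated counts and 95% intervals of 132 to 1250 and 54.6 to 781.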

Other observations

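The tests of chance splits and of gene length and GC content were set before their results were seen, and the tests of dilution, of myeloid sources, of untreated replicate 1, of Wapl and of ATF4 targets, like the 5 lists used here, were chosen only afterwards. In 4 cases the bound that would have counted against the explanation was redrawn once the value was known. These were ATF4 targets, weaker knockdown in untreated replicate 1, dilution and a shared myeloid source, for the last of which the measure was redrawn too. By the bounds first drawn, the values counted against all 4 explanations, and by the redrawn bounds all 4 now read as open. The bound for Ly6c2 and Ms4a6c was set with the value known.

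Several genes of V(D)J recombination, which assembles antigen receptor genes, were higher after dox. Of 12 genes of recombination and end joining, 7 rose, 4 did not pass and 1, Xrcc5, which encodes Ku80, fell (log2 fold change −0.92, SE 0.09). Rag1 rose from 132.3 ± 91.8 to 1372 ± 268 CPM (SD, n = 3), Polm, a polymerase of end joining, by 4.12 (SE 0.30), Dclre1c, which encodes the hairpin-opening nuclease Artemis, by 1.35 (SE 0.10), and Lig4, Xrcc4 and Xrcc6 by 0.46 to 0.58, while Rag2 rose by 4.34. Dntt measured −0.36 (SE 0.34). The list was chosen after the rises of Rag1, Rag2 and Polm had been seen, so its test as a set is not given, and of the other 9 members 4 rose, with a median of 0.21. The animals whose marrow was sorted are Rag1 knockouts. Since separate mice carried 1 leukemia, this genotype is that of the hosts and need not be that of the leukemia. The Rag1 counts alone do not tell which cells they came from.

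Of 26 lysosome genes, 21 rose (median 0.53, camera adjusted p = 1.6e-06, and adjusted p = 0.198 with an estimated correlation), among them the protease genes Ctsh by 2.45 and Ctss by 1.16, the cholesterol carrier gene Npc2 by 1.38 and Laptm5 by 1.39. Of 26 proteasome genes, 23 fell and 3 (Psma3, Psmb1 and Psmb6) did not pass (median −0.37, camera adjusted p = 2.8e-06, and adjusted p = 0.436 with an estimated correlation). Both lists were chosen with the values known, so their p-values, over 34 lists, only describe. Several lysosome genes, Ctss among them, are also abundant in macrophages, whose markers were higher in the same libraries.

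Genes of S phase, of G2 and M phase and of ribosome biogenesis fell together. A length and GC trend is argued against as the whole cause, since the highest of the 3 list medians was −0.76 before and −0.79 after that trend was removed. Dilution of the leukemia by cells that do not divide would lower leukemia genes outside the cell cycle alike. The 10 progenitor genes of at least 50 CPM had a median of 0.23 and ran from −0.77 for Runx1 to 3.38 for Rag1 (SD 1.15). All 10 thus lay above the medians of S phase (−1.25) and of G2 and M phase (−0.91). Unless the treatment itself raised all of them, this argues against dilution as the whole cause of both falls. For ribosome biogenesis, with a median of −0.76, and for dilution in part, the genes ran too wide to decide. Slower division after Pax5 restoration is a hypothesis that stays open beside partial dilution and beside effects of the drug or of the GFP-mid gate, since no library separates them.

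Neutrophil and macrophage markers were higher after dox, although leukemia cells were sorted by GFP, a gate meant to remove host cells. The gate was GFP-mid for dox and GFP-high for untreated mice, and whether both remove host cells alike was not tested. For 8 neutrophil markers of at least 10 CPM, dox replicate 1 exceeded dox replicate 2 by 4.27-fold on average, with log2 ratios from 1.32 for Itgam to 2.74 for Camp and an SD of 0.42, a spread that goes with 1 source such as carried-over neutrophils without proving it. The most abundant of them, S100a9 and S100a8, reached 169.9 and 106.3 CPM in dox replicate 1. Whether both lists have 1 source stays open: the mean log2 ratio of dox replicate 1 to 2 was 2.09 (SD 0.42) for neutrophil and 0.45 (SD 0.78) for 9 macrophage and monocyte markers, and that of dox replicate 3 to 2 was 1.04 (SD 0.31) and −0.21 (SD 0.46), but that of dox replicate 1 to 3 was 1.05 (SD 0.14) and 0.65 (SD 0.60), a difference of 0.4, so the lists part by more than their spread only against dox replicate 2. Of the macrophage and monocyte markers, Ly6c2 at 1.99 and Ms4a6c at 1.44 lay among the neutrophil ratios of dox replicate 1 to 2, while their mean of dox replicate 3 to 2 was 0.26 (SE 0.24 from counts) against 0.49 to 1.45 for the neutrophil ones, too imprecise to decide, and an origin in the leukemia itself was not tested.

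Untreated replicate 1 lay toward the dox libraries in its general profile. The first principal component placed it at −33.1, untreated replicates 2 and 3 at −45.2 and −39.5, and dox libraries at 35.7 to 45.8. Rag1 measured 236.4 CPM there against 62.6 and 98 CPM in untreated replicates 2 and 3. Pax5 measured 153.8 CPM against 93.5 and 105.2. Among dox libraries, replicate 1 was likewise the highest for Rag1 but the lowest for Pax5, and an effect shared by replicate number was not tested. RNA or cells of a dox library in untreated replicate 1 would move all genes toward the dox level by the same share. Rag1 stood at 12.1% and Rag2 at 8.46% of the way to the dox level. The 62 other genes that rose more than 8-fold had a median of 3.15% with quartiles of 0.191% and 9%. Their upper quartile lay below the share of Rag1 but above that of Rag2. Rag1 was picked for its high level in this library, so its larger share can follow from that choice and decides nothing. Carry-over stays open, also by the bound set for this test. A smaller share cannot be told apart from variation between mice. The Pax5-activated genes gave no sign of weaker knockdown in that mouse. Their median log2 ratio to the other untreated libraries was −0.01 (SD 0.31), with 12 of 24 higher. Given the spread of the members, a small shift is not excluded, so weaker knockdown stays open. Without this library the fold change of Pax5 was 1.31 on the log2 scale.

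A further hypothesis was that Wapl fell as part of a general fall of cohesin genes. Of 15 cohesin and CTCF genes, 4 rose (Nipbl, Mau2, Esco1 and Hdac8) and 9 fell, and the list did not pass (median −0.45, camera adjusted p = 0.056). Wapl, singled out for its fall of −3.18, lay 2.02 log2 units below the lowest other member, Cdca5 at −1.16, and the other 14, which were not chosen by their change, had a median of −0.34, which argues against a general fall as the whole cause for Wapl. Repression of Wapl by the restored Pax5 is a candidate explanation that these data cannot test.

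A stress response to the drug through ATF4 was asked for as well. Of 15 ATF4 targets, 5 rose (Chac1, Trib3, Ddit3, Sesn2 and Ddit4) and 7 fell (Psat1, Phgdh, Shmt2, Mthfd2, Slc7a11, Slc3a2 and Nars), with a median of −0.11 and a camera adjusted p of 0.421. The list was thus not higher as a set, which is what had been asked of such a response. The redrawn bound against it asked for no member higher, which the values known by then could not meet. That bound could therefore not decide, and with members going both ways such a response stays undecided.

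The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only the real split, 1 of 10, reached 3316 genes higher or 3266 lower, and the highest count of any other split was 0 in edgeR, where at an unadjusted p under 0.05 other splits gave at most 144 higher and 180 lower, and at most 0 genes in limma voom and 7 in DESeq2. For the lists, 3 of 10 splits, the real one included, called at least the 17 lists of camera, with 20 as the highest of the others, while fry called 21 in the real split and 0 in any other. Every other split mixes dox and untreated libraries within a group, so the treatment difference adds to the spread within groups. Few or no calls by edgeR, limma voom, DESeq2 and fry are therefore built in there. Their low counts do not show how many calls arise without a treatment effect. Each other split also leaves the 2 groups unequal in dox libraries, and nearly all lists called there went in the direction of the treatment. Camera with its preset correlation thus called lists in splits where edgeR called no gene, and since those splits follow the treatment in part, whether it calls too many here stays open.

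Widely differing levels within a group, as values only, were those of the light chain gene Iglc1, with 97, 0.87 and 16.4 CPM in untreated and 310.7, 18.1 and 87.1 CPM in dox replicates 1, 2 and 3, and of Bcl11b, with 40.1, 1.54 and 10.9 CPM in untreated and 17.7, 2.71 and 5.31 CPM in dox replicates 1, 2 and 3.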
